A study of Mus musculus with 6 samples.

How the data were processed

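RNA was measured by sequencing in natural killer (NK) cells sorted from mouse spleen. Per the labels' protocols, spleen cells of 20 C57BL/6Ncr mice aged 6 to 8 weeks were enriched for NK cells on a magnetic column, their Fc receptors were blocked with antibody 2.4G2, and CD3-negative NK1.1-positive cells were sorted by flow cytometry into a Ly49G-positive, Ly49C/I-negative population and a Ly49G-negative, Ly49C/I-positive population. Antibody 4D11 marked Ly49G, and a single antibody that binds both Ly49C and Ly49I marked Ly49C/I. The populations are called Ly49G+ and Ly49I+ here, with 3 libraries each. The labels call these biological replicates, but do not say how many mice fed each replicate, so p-values measure the spread between these libraries.

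Per the labels' protocols, strand-specific libraries were made from 0.4 µg of total RNA and sequenced on a HiSeq2000 as pairs of 100-base reads. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.3.0, limma and the mouse genome build mm10 were used. The read counter, the gene annotation and the filter on low genes are not given in the sources used here. The table the authors deposited holds log2 CPM (counts per 1000000 reads of the library) for 8520 genes, identified by NCBI gene number. Its values follow the formula of limma's voom: 0.5 was added to each count, 1 to the library total, and the ratio was scaled to 1000000 before taking the logarithm. Solving that formula gave whole reads for 100% of values within a tolerance of 0.001 read. The library totals came out as whole numbers, so no further scaling between libraries had been applied to the deposited log2 values. Every listed gene reached 10 CPM in at least 2 libraries, the lowest second-highest value being 10.0. Genes outside the table held 1.43% to 1.71% of each library's reads, and no statement is made about them.

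Library totals were 33599679, 36126707 and 37308068 reads for Ly49G+ replicates 1, 2 and 3, and 34634383, 40892154 and 39016017 for Ly49I+ replicates 1, 2 and 3. The smallest count of any listed gene was 8 reads and the median gene had between 1567.5 and 1945.5 reads per library, so the spread between libraries, not counting error, limits the precision of most genes. No pair of replicates agreed within sampling noise, and each library was counted once. Gene names were matched by gene number to the RefSeq table of assembly GRCm38.p6 for 8429 genes and to GENCODE for 1 gene, and 90 genes found no name. Coordinates are those of GRCm38.p6, the assembly that mm10 represents.

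The groups were compared with limma 3.58.1 in R 4.3.3 on the deposited log2 values, with a linear model per gene, empirical Bayes moderation with an intensity trend, a two-sided test of Ly49G+ minus Ly49I+, and Benjamini-Hochberg adjustment over the 8520 genes at 0.05. All adjusted p-values for single genes come from this limma test unless stated. A design for raw counts was not needed, since the unit was log2. On simulated data made from these libraries' means and totals with 200 of 8520 genes changed, the same steps called 46% of genes changed by 0.5 on the log2 scale, 92% of those changed by 1 and 98% of those changed by 2, with 6 false calls, and made 0 calls when nothing was changed. The simulation drew each gene independently, without effects shared by the genes of a library, so its false calls may differ from those in the real libraries. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

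Fixed before the data were examined were the test, the alternatives, the rule for named genes and 27 gene lists with 780 members, of which 534 were measured. The lists cover the Ly49 family, other NK complex lectins, co-stimulatory and inhibitory receptors, ITAM and ITIM signalling, cytotoxic effectors, cytokines and chemokines, cytokine receptors, NK maturation at the CD11b+ stage, NK maturation at the CD27+ or immature stage, type 1 innate lymphoid cells (ILC1) and tissue residency, NK transcription factors, trafficking receptors, proliferation, immediate early and handling response, interferon response, MHC class I and antigen processing, glycolysis, mitochondrial oxidative phosphorylation, cytosolic ribosomal proteins and mitochondrial transcripts. Markers of other cells that the sort could hold form the B cell, T cell, myeloid and dendritic cell, erythroid, platelet, and stromal and endothelial lists, and sex-linked genes form the last. The 21 lists with 5 or more measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way, were alternatives. Genes named in the text are every measured Ly49 gene, the 12 largest differences in each direction among genes past the threshold with fully separated groups and a mean of at least 1 on the log2 scale in the higher group, and up to 4 members past the threshold from each list, or up to 2 members given as values where none passed. Of the genes this rule selects, 1 is not reported here. Other genes named were chosen after their values were seen.

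Replicates share numbers between the groups. The deviations of same-numbered libraries from their group means correlated across genes at 0.371, 0.114 and 0.156, each above the limit of 0.1 set beforehand for treating the numbers as pairs, although only 3 of the 6 libraries correlated best with their own number and replicate 3 of Ly49G+ correlated at 0.359 with replicate 2 of Ly49I+. The labels do not say what a number shares. Results from a fit with the replicate block are therefore printed where they change a call or move a count by more than 1.5 times. The other alternatives were no intensity trend, a robust prior, minimum gene means of 1 and 4 on the log2 scale, quantile normalization, median centring, a test against a 1.2-fold change, and leaving out each library in turn. Voom precision weights, a list of ribosome assembly factors and the comparisons of excess CPM between libraries were added after seeing the data. No sample was left out of the main comparison.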

Results

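NK cells of C57BL/6 mice each express some members of the Ly49 receptor family, which bind MHC class I molecules, and the series asks how transcription differs between splenic NK cells that carry Ly49G and those that carry Ly49I. RNA was compared between 3 Ly49G+ and 3 Ly49I+ libraries, sorted as Ly49G-positive and Ly49C/I-negative or the reverse. Library totals ran from 33599679 to 40892154 reads. Of 8520 genes, 306 differed between the populations in the limma test at an adjusted p of 0.05, 155 higher in Ly49G+ and 151 higher in Ly49I+ cells.

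Ly49I+ cells had more RNA for genes of the CD11b+ stage of NK maturation, with 15 of 22 higher, including the fractalkine receptor gene Cx3cr1 (log2 difference of Ly49G+ minus Ly49I+ -2.06 ± 0.09, SE, 3 libraries per group). In Ly49G+ libraries 12 of 23 genes of the CD27+ or immature stage were higher, including the interleukin 7 receptor gene Il7r (1.99 ± 0.13), as were 6 of 9 T cell markers, 10 of 77 ribosomal protein genes and 4 of 31 proliferation genes. With an estimated correlation between genes the CD11b+ list kept its call (adjusted p = 0.02), and the immature stage (adjusted p = 0.287), T cell (0.161), ribosomal (0.443) and proliferation (0.287) lists did not. Csf1r and Lyz2, genes known from monocytes and macrophages, were higher in Ly49I+ libraries. Most differences were small: 16 genes were at least 2-fold higher in Ly49G+ and 47 at least 2-fold higher in Ly49I+, while 89 and 66 called genes differed by less than 1.5-fold. The 47 include 27 genes at least 4-fold higher, Klra9 apart, most of them far higher in Ly49I+ replicate 2 than in the other Ly49I+ libraries. The median called gene was 1.46-fold higher in Ly49G+ or 1.61-fold higher in Ly49I+. All 306 called genes had fully separated groups, which a call with 3 libraries per group nearly requires. Across all genes 2199 (25.8%) had separated groups, where chance gives 10% on average over splits. Genes of a library can move together, so a single split can lie far from 10%, and the share in other splits was not computed.

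The number of genes called changed when single libraries were left out, which also lowers the power of the test. It was 155 without Ly49G+ replicate 1, 94 without Ly49G+ replicate 2, 168 without Ly49G+ replicate 3 and 644 without Ly49I+ replicate 1. Without Ly49I+ replicate 2, in which Ace, Csf1r and Lyz2 were highest, 207 genes were called, 110 higher in Ly49G+ and 97 higher in Ly49I+, and 187 of the 306 were among them. With the replicate block 993 genes were called, 485 higher in Ly49G+ and 508 higher in Ly49I+, and these contained all 306.

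The sorted receptors came first as a check of the labels, since cells chosen on a protein should carry its RNA. Klra7, which encodes Ly49G (gene 16638, GRCm38.p6 chromosome 6, 130218605 to 130233322), stood at 974 ± 59.9 CPM (counts per 1000000 reads) in Ly49G+ and 11.22 ± 0.475 in Ly49I+ cells (SD, n = 3 each), so the Ly49I+ level was 1.15% of the Ly49G+ level. Klra9, which encodes Ly49I (gene 16640, chromosome 6, 130178626 to 130194374), stood at 78.11 ± 5.29 in Ly49G+ and 1068 ± 110 in Ly49I+ cells, so 7.32% of the Ly49I+ level was found in Ly49G+ cells. The log2 differences were 6.44 ± 0.08 for Klra7 (adjusted p = 4.56e-12) and -3.77 ± 0.09 for Klra9 (adjusted p = 2.33e-09). Klra3, which encodes Ly49C, the other target of the Ly49C/I antibody (gene 16634, chromosome 6, 130323289 to 130337626), was not lower in the cells sorted as Ly49C/I-negative. Its level was 248 ± 6.26 CPM in Ly49G+ and 201.2 ± 16.3 in Ly49I+ cells (log2 difference 0.30 ± 0.08, adjusted p = 0.0604, and 0.0109 with the replicate block). Without Ly49I+ replicate 1 its adjusted p was 0.0396.

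Of 11 measured members of the Ly49 family, 5 were higher in Ly49G+ cells, 1 was higher in Ly49I+ cells and 5 did not pass. Adjusted over the list alone, 8 were higher and 1 lower in Ly49G+. Besides Klra7, the genes higher in Ly49G+ were Klra1 (Ly49A, 141.9 ± 19.6 against 57.49 ± 6.54 CPM, SD, adjusted p = 0.000303), and, as log2 differences, Klra6 (Ly49F, 0.85 ± 0.12), Klra4 (the activating receptor Ly49D, 0.83 ± 0.10) and the pseudogene Klra13-ps (0.70 ± 0.12). Klra13-ps lost its call without Ly49G+ replicate 1 or 2. Klra8 (Ly49H) differed by 0.37 ± 0.11 (adjusted p = 0.103, and 0.00517 with the block) and Klra10 by 0.42 ± 0.17 (adjusted p = 0.206, and 0.00864 with the block). Both also passed without Ly49I+ replicate 1. Klra5 (0.26 ± 0.15, adjusted p = 0.354) and Klra14-ps (-0.02 ± 0.12, adjusted p = 0.938) did not pass. As a list the family was higher in Ly49G+ (camera adjusted p = 4.02e-07), a call lost with an estimated correlation (adjusted p = 0.437). The list includes the sorted receptors Klra7 and Klra9, so its test is not independent of the sort. How the authors' counting treated reads shared between these near-identical genes is not given in the sources used here, so the levels of single Ly49 genes are uncertain. Klra8 and Klra14-ps share 14.4% and 13.3% of their 100-base transcript windows with another Ly49 gene, Klra10 shares 5.2%, Klra9 4.1%, Klra13-ps 1.9%, Klra7 1.8%, and Klra1, Klra4, Klra5 and Klra6 share 0.

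**Figure D1:**
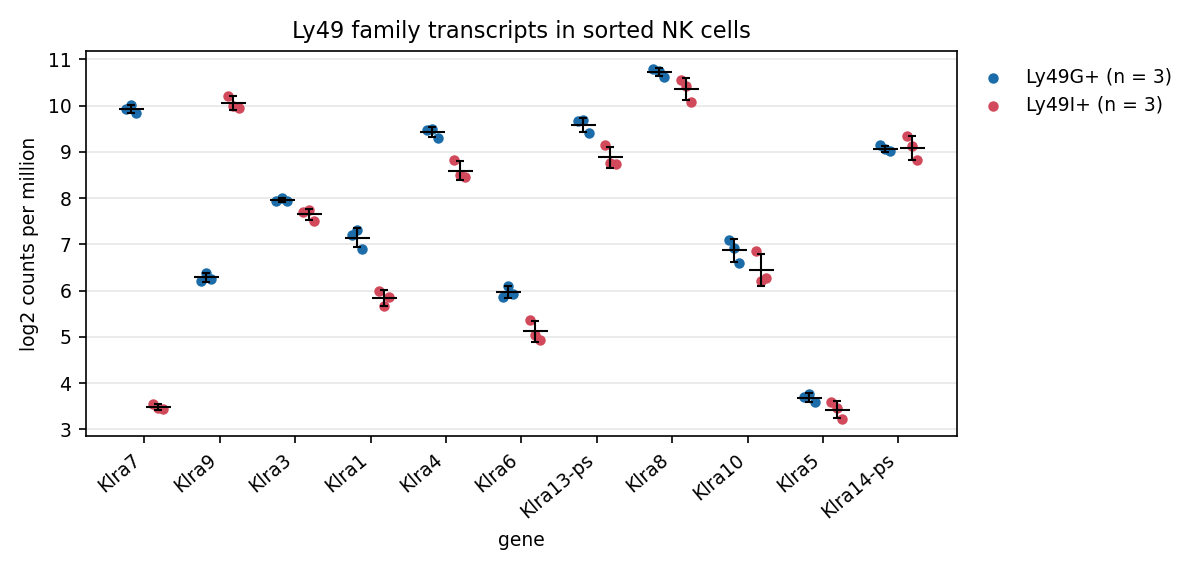
Log2 CPM of the 11 measured Ly49 genes, with each point a library, the wide bar the group mean and the error bar 1 SD (n = 3 per group). The log2 difference of Ly49G+ minus Ly49I+ is 6.44 for Klra7, -3.77 for Klra9 and 0.30 for Klra3.

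Genes of the CD11b+ stage, the late stage of NK maturation, were lower in Ly49G+ than in Ly49I+ cells. Of 22 measured members 15 were higher in Ly49I+, 0 were higher in Ly49G+ and 7 did not pass. Adjusted over the list alone, 18 were higher in Ly49I+ and 1 in Ly49G+. Cx3cr1 led (adjusted p = 6.82e-07), followed by Klrg1, an inhibitory lectin of mature NK cells (-1.26 ± 0.07, adjusted p = 1.09e-05), Ly6c2 (-1.13 ± 0.12, adjusted p = 0.000812) and S100a6 (-0.72 ± 0.10, adjusted p = 0.00355). This list passed camera at an adjusted p of 5.25e-16 and was the only one of 21 to pass with an estimated correlation (adjusted p = 0.02). The count fell to 8 without Ly49G+ replicate 1, 6 without Ly49G+ replicate 2, 8 without Ly49G+ replicate 3 and 10 without Ly49I+ replicate 2, and was 9 without the intensity trend.

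Genes of the CD27+ or immature stage moved the other way. Of 23 measured members 12 were higher in Ly49G+, 0 were higher in Ly49I+ and 11 did not pass. Adjusted over the list alone, 16 were higher and 1 lower in Ly49G+. Examples are Il7r (adjusted p = 1.84e-05), Ctla2a (0.85 ± 0.07, adjusted p = 0.000221), the receptor gene Cd160 (0.92 ± 0.08, adjusted p = 0.000294) and Emb (0.83 ± 0.10, adjusted p = 0.00208). Camera gave an adjusted p of 1.14e-13, and 0.287 with an estimated correlation. Without Ly49G+ replicate 2 or replicate 3 the count was 6, without Ly49I+ replicate 2 it was 11 and without the intensity trend 7. In the list of type 1 innate lymphoid cells (ILC1) and tissue residency 3 of 9 measured genes were higher in Ly49G+ and 6 did not pass, with 4 higher and 2 lower adjusted over the list alone. With the block 4 were higher and 1 lower. The 3 were Il7r, Cd3g and the interleukin 21 receptor gene Il21r (0.69 ± 0.09), the first shared with the immature stage list and Cd3g with the T cell list. Camera gave an adjusted p of 0.000294, and 0.287 with an estimated correlation.

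**Figure D2:**
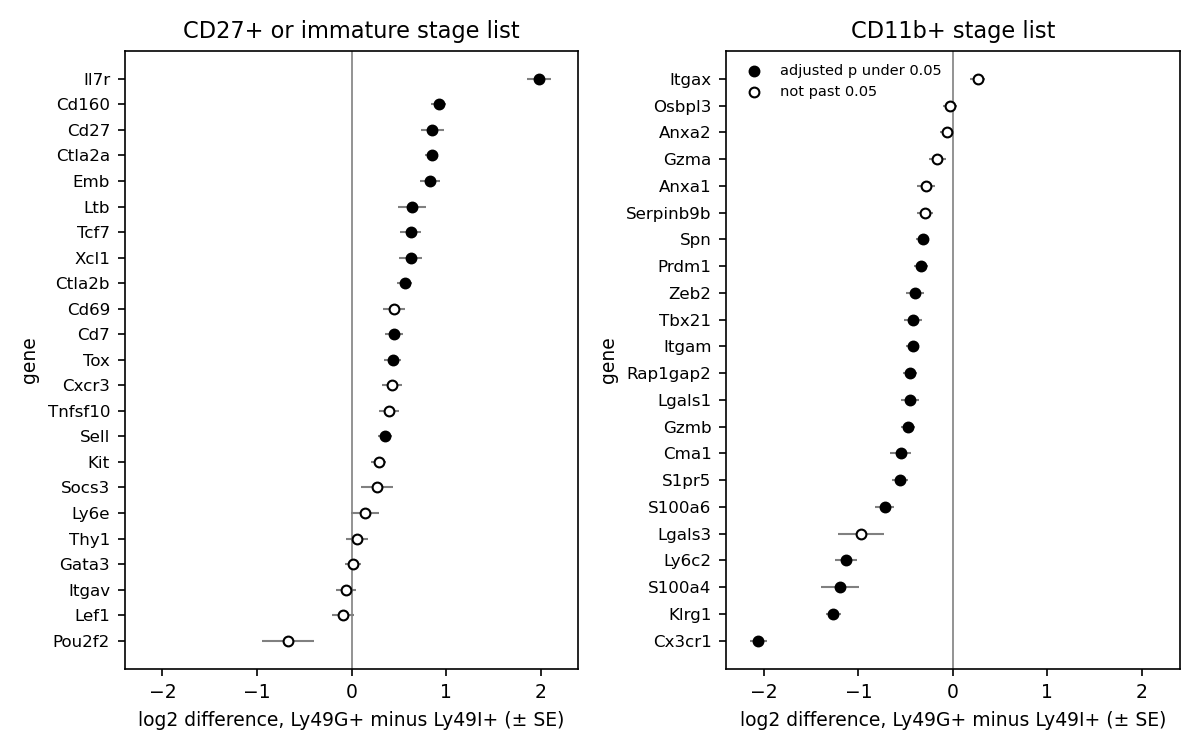
Log2 difference of Ly49G+ minus Ly49I+ for the measured members of the NK maturation lists, with bars of 1 SE from limma (3 libraries per group). Filled points passed the adjusted p of 0.05: 12 of 23 in the CD27+ or immature list, all above 0, and 15 of 22 in the CD11b+ list, all below 0.

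Transcripts of T cell markers were higher in the Ly49G+ libraries, although both populations were sorted as CD3-negative. Of 9 measured members 6 were higher in Ly49G+, 0 were lower and 3 did not pass, and 9 were higher adjusted over the list alone. They include Cd3e (3.78 ± 0.40, adjusted p = 0.000816), the T cell receptor alpha constant gene Trac (1.92 ± 0.25, adjusted p = 0.00295), Cd3g (1.70 ± 0.16, adjusted p = 0.000543) and the co-stimulatory receptor gene Cd28 (0.70 ± 0.08, adjusted p = 0.0012). Camera gave an adjusted p of 1.09e-12, and 0.161 with an estimated correlation. With a minimum mean of 4 on the log2 scale, which left 6 of the members, 3 were called. Cd3e stood at 9.271, 18.53 and 11.49 CPM in Ly49G+ replicates 1, 2 and 3, and at 0.5919, 1.064 and 1.217 in the Ly49I+ replicates. The immature stage, ILC1 and ribosomal lists shared the direction toward Ly49G+ in camera, a call each lost with an estimated correlation. Within Ly49G+ the T cell and ILC1 list means were highest in replicate 2, at 5.804 and 5.508 log2 CPM. The immature stage list mean was 6.8, 6.945 and 6.958 in Ly49G+ replicates 1, 2 and 3, so replicates 2 and 3 were nearly level. The ribosomal list mean was highest in replicate 3, at 7.995.

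Outside the Ly49 family the largest differences toward Ly49I+ were led by Ace (-5.44 ± 0.60, adjusted p = 0.00112), the adhesion receptor gene Adgre4 (-5.22 ± 0.55), Grk3 (-4.92 ± 0.57), Treml4 (-4.77 ± 0.58), Cd300ld (-4.73 ± 0.58) and Sirpa (-4.32 ± 0.59), followed by Csf1r, the receptor for macrophage colony-stimulating factor (-4.04 ± 0.56), Ifitm3 (-4.02 ± 0.80), Tlr13 (-3.97 ± 0.58), Ceacam1 (-3.84 ± 0.61) and Cybb (-3.70 ± 0.54). Of the myeloid and dendritic cell list only 3 of 35 members were measured, too few for a list test. Csf1r and the lysozyme gene Lyz2 (-3.45 ± 0.55, adjusted p = 0.00701) passed, and Cst3 did not (-0.79 ± 0.28, adjusted p = 0.154, and 0.0477 with the block). Adjusted over the list alone 3 passed, as they did without Ly49I+ replicate 1. The spread within Ly49I+ was wide, as in Ace at 60.79, 201.3 and 44.79 CPM in replicates 1, 2 and 3, against 1.146, 1.204 and 4.865 in Ly49G+. Over the 27 genes at least 4-fold higher in Ly49I+, Klra9 apart, the median was 17.94, 50.66 and 11.57 CPM in Ly49I+ replicates 1, 2 and 3. In the Ly49G+ replicates it was 1.205, 1.896 and 3.069. The CD11b+ stage list shared their direction between the groups, but not their spread within Ly49I+. Its mean log2 CPM was 8.268, 8.309 and 8.309 in Ly49I+ replicates 1, 2 and 3. Ifitm3 lost its call without Ly49I+ replicate 2 (adjusted p = 0.0745) and without the intensity trend (0.0518), and Ifitm3, Ceacam1 and Lyz2 lost theirs without Ly49G+ replicate 2. With limma's robust prior, which allows genes of unusual spread, Ace (adjusted p = 0.0562), Csf1r (0.0910), Ifitm3 (0.0933), Ceacam1 (0.0625), Cybb (0.0983) and Lyz2 (0.125) did not pass.

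**Figure D3:**
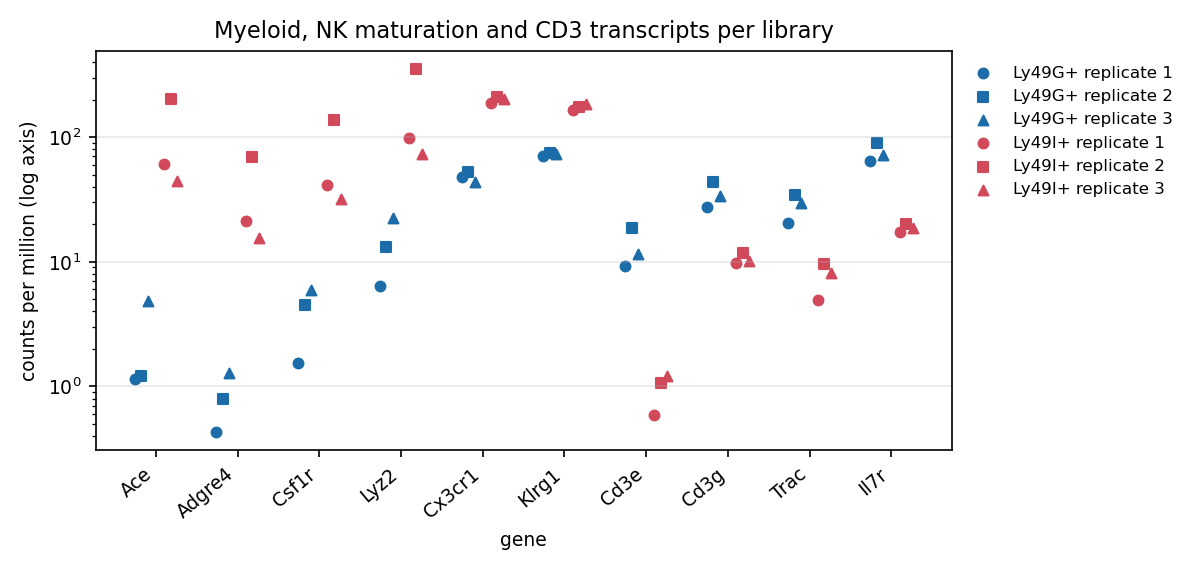
CPM on a log axis for each library, with replicates 1, 2 and 3 as circle, square and triangle. Ace reaches 201.3 in Ly49I+ replicate 2 against 44.79 in replicate 3, while Cx3cr1 lies at 207.8 and 203.5 in the same libraries.

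Toward Ly49G+ the largest differences outside the Ly49 family, the CD3 chains and Trac were in Il7r, Dpysl5 (1.69 ± 0.23), the SLAM family receptor gene Slamf6 (1.52 ± 0.17), Gpr55 (1.40 ± 0.19), Chl1 (1.36 ± 0.20), the Notch ligand gene Dll1 (3.68 ± 0.22 against 2.48 ± 0.28 log2 CPM, SD), the transcription factor gene Sox6 (1.15 ± 0.17) and Csf2, which encodes the cytokine GM-CSF (1.11 ± 0.15). Cd3d differed by 1.34 ± 0.19. Dll1 lost its call without Ly49G+ replicate 2. Co-stimulatory and inhibitory receptors were higher in Ly49G+ in 4 of 19 measured members, lower in 0 and not past the test in 15, with 5 higher adjusted over the list alone. The 4 were Slamf6, Cd160, Cd27 (0.85 ± 0.12) and Crtam (0.72 ± 0.09). Camera gave an adjusted p of 0.00348, and 0.443 with an estimated correlation. With the replicate block 7 members were called.

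Of 77 measured ribosomal protein genes 10 were higher in Ly49G+, 0 were lower and 67 did not pass, and 27 were higher adjusted over the list alone. The groups overlapped in mean log2 CPM over the list, at 7.86, 7.91 and 8.00 in the Ly49G+ libraries and 7.51, 7.66 and 7.93 in the Ly49I+ libraries. Rpl23 (0.48 ± 0.06, adjusted p = 0.00295), Rpl5 (0.45 ± 0.08), Rps6 (0.43 ± 0.08) and Rps15a (0.44 ± 0.08) had the smallest p. Camera gave an adjusted p of 7.29e-16, and 0.443 with an estimated correlation, and fry gave 0.182. With the block 36 members passed. Leaving out Ly49G+ replicates 1, 2 and 3 left 6, 1 and 4, and leaving out Ly49I+ replicates 2 and 3 gave 5 and 29. Without the intensity trend 4 passed. Proliferation genes were higher in Ly49G+ in 4 of 31 measured members, lower in 0 and not past the test in 27, with 8 higher adjusted over the list alone. They were the kinetochore motor gene Cenpe (0.62 ± 0.10), Tpx2 (0.61 ± 0.11), Mki67 (0.43 ± 0.09, not past without the trend) and the topoisomerase gene Top2a (0.42 ± 0.08). Camera gave an adjusted p of 4.02e-07, and 0.287 with an estimated correlation. With the block 8 passed, without Ly49G+ replicate 1 there were 2, and without Ly49G+ replicate 2 there were 0.

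The other 13 tested lists did not pass camera. NK transcription factors went both ways, with 6 of 48 higher in Ly49G+, 5 higher in Ly49I+ and 37 not past the test (adjusted p = 0.643). Ikzf2, which encodes Helios (1.07 ± 0.11), Tcf7 (0.63 ± 0.11), Aff3 (0.54 ± 0.07) and Eomes (0.39 ± 0.07) were higher in Ly49G+. The total of 11 was 4 without Ly49G+ replicate 1, 2 without either of the other Ly49G+ replicates, 6 without Ly49I+ replicate 2 and 6 without the trend. Adjusted over the list alone, 6 were higher and 7 lower in Ly49G+. Trafficking receptors had 3 of 24 higher in Ly49G+ and 6 higher in Ly49I+ (adjusted p = 0.41, 0.0305 toward Ly49I+ by fry, and 7 and 9 adjusted over the list alone). The chemokine receptor gene Ccr2 was higher in Ly49G+ (0.61 ± 0.08), and Cx3cr1, Cmklr1 (-0.74 ± 0.10) and S1pr5 (-0.56 ± 0.09) were higher in Ly49I+. The total of 9 was 14 with the block and 4, 3 and 5 without Ly49G+ replicates 1, 2 and 3. Other NK complex lectins had 3 of 16 higher and 3 lower in Ly49G+ (adjusted p = 0.156, and 6 and 3 adjusted over the list alone). Klri1 was higher (0.66 ± 0.11), and Klrg1, Klrb1b (-0.97 ± 0.08) and Klrc1, which encodes NKG2A (-0.56 ± 0.08), were lower. The total of 6 was 3 without Ly49G+ replicate 1 or 2.

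Called cytotoxic effectors and cytokine receptors went both ways, while called cytokines and chemokines were all higher in Ly49G+. Cytotoxic effectors had 1 of 19 higher in Ly49G+, Serpinb6b (0.39 ± 0.07), and 2 higher in Ly49I+, granzyme B gene Gzmb (-0.47 ± 0.07) and perforin gene Prf1 (-0.49 ± 0.10, adjusted p = 0.0253). The list gave an adjusted p of 0.578, with 2 higher and 4 lower in Ly49G+ adjusted over the list alone. The total of 3 was 8 with the block, 5 without Ly49I+ replicate 1, 0 without Ly49G+ replicate 2 and 1 without Ly49G+ replicate 3. Cytokines and chemokines had 3 of 12 higher in Ly49G+, namely Csf2, Xcl1 (0.63 ± 0.12) and Ltb (0.64 ± 0.15), the last pair not past without the trend, and 0 lower (adjusted p = 0.792, and 3 and 1 adjusted over the list alone). With the block 5 were called, and without Ly49G+ replicate 2 or 3 or without the trend there was 1. Cytokine receptors had Il7r, Il21r and Il6st (0.82 ± 0.13) higher and Tgfbr3 (-1.39 ± 0.27) lower in Ly49G+ among 21 (adjusted p = 0.643, and 5 and 5 adjusted over the list alone). The total of 4 was 10 with the block, 7 without Ly49I+ replicate 3 and 2 without Ly49G+ replicate 2.

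ITAM and ITIM signalling had 1 of 31, Fcer1g (-0.34 ± 0.08, adjusted p = 0.0441), higher in Ly49I+ (list adjusted p = 0.643, and 1 adjusted over the list alone). Fcer1g lost its call without the intensity trend (adjusted p = 0.1) and without any single library but Ly49I+ replicate 1. The count was 2 with the block and 2 without Ly49I+ replicate 1. Immediate early and handling genes had 1 of 36 called, the phosphatase gene Dusp2 (-0.47 ± 0.08), also 1 adjusted over the list alone (list adjusted p = 0.643). With the block 6 were called, without Ly49I+ replicates 1 and 2 there were 4 and 2, and without Ly49G+ replicate 2 there were 0 (Dusp2 adjusted p = 0.0649). Glycolysis had Pdk1 (0.80 ± 0.11) higher and the glucose transporter gene Slc2a3 (-0.37 ± 0.08) lower in Ly49G+ among 17, also 1 and 1 adjusted over the list alone (list adjusted p = 0.643). Slc2a3 lost its call without the trend and without any single library but Ly49I+ replicate 1. The total of 2 was then 1, and it was 4 with the block and 4 without Ly49I+ replicate 1. In limma's test 0 of 28 interferon response genes passed (list adjusted p = 0.251, with 3 higher adjusted over the list alone and 3 with the block), Ifi44 (0.78 ± 0.19, adjusted p = 0.0526, and 0.016 with the block) and Ifit1 (0.52 ± 0.13, adjusted p = 0.0548, and 0.026 with the block) being nearest. Both also passed without the intensity trend, with the robust prior and after either rescaling. Without Ly49I+ replicate 1 the count was 2, higher in Ly49G+, and without Ly49I+ replicate 3 it was 1, higher in Ly49I+. In limma's test 0 of 22 MHC class I and antigen processing genes passed, 0 adjusted over the list alone and 2 with the block (list adjusted p = 0.643), with Erap1 at 0.24 ± 0.07 (adjusted p = 0.103, and 0.0353 with the block) and B2m at 0.37 ± 0.13 (adjusted p = 0.148, and 0.0202 with the block). B2m passed without Ly49I+ replicate 2 (adjusted p = 0.0467), and the list passed toward Ly49G+ without Ly49I+ replicate 3 (adjusted p = 0.0178). In limma's test 0 of 43 oxidative phosphorylation genes passed, 0 adjusted over the list alone and 2 with the block (list adjusted p = 0.951), with Ndufb8 at -0.55 ± 0.15 (adjusted p = 0.0783, and 0.0309 with the block) and Uqcrb at 0.29 ± 0.10 (adjusted p = 0.138, and 0.0221 with the block).

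Calls of other named genes also changed when 1 library was left out. Such a fit has fewer libraries and less power, so a lost call does not by itself show that 1 library carried the difference. Prf1 did not pass without Ly49G+ replicate 1 (adjusted p = 0.113), 2 (0.168) or 3 (0.0633), without Ly49I+ replicate 2 (0.054) or without the trend (0.0691), and Ltb did not pass in the same fits. Mki67 and Tgfbr3 did not pass without Ly49G+ replicate 1 or 2 or Ly49I+ replicate 2. Eomes lost its call without any single Ly49G+ replicate, although its log2 difference stayed at 0.398, 0.386 and 0.399 without Ly49G+ replicates 1, 2 and 3. Klri1 and Top2a lost theirs without Ly49G+ replicate 1 or 2. Rpl5, Rps6, Serpinb6b, Tcf7, Tpx2, Xcl1 and Cd22 lost theirs without Ly49G+ replicate 2 or 3, and Cenpe, Gzmb, Il6st, Rps15a and S1pr5 without Ly49G+ replicate 2. Against a 1.2-fold change, 3 CD11b+ stage, 5 immature stage, 5 T cell, 0 ribosomal and 0 proliferation genes passed, along with 1 transcription factor, 3 trafficking receptors, 2 other lectins, 2 cytokine receptors, 1 cytokine and 0 cytotoxic effectors.

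Among markers of other cells, 1 of 7 B cell genes, Cd22, was higher in Ly49G+ (0.93 ± 0.17, adjusted p = 0.0131, also 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.522, and 0.0261 toward Ly49G+ without Ly49I+ replicate 2). The count was 2 with the block, 2 without Ly49I+ replicate 2 and 0 without Ly49G+ replicate 2 or 3. Mean log2 CPM over the B cell list was uneven within both groups. It was 4.261, 4.779 and 5.505 in Ly49G+ replicates 1, 2 and 3, and 4.394, 5.755 and 4.827 in the Ly49I+ replicates. The mean log2 difference over the list was -0.144, although camera's direction was toward Ly49G+. Lists with fewer than 5 measured members were not tested as lists. In limma's test 0 of 4 erythroid genes passed, with 2 higher adjusted over the list alone and 2 with the block, Tfrc (0.57 ± 0.15, adjusted p = 0.0591, 0.00345 with the block, 0.0405 after quantile normalization and 0.0433 after median centring) and Car2 (0.25 ± 0.09, adjusted p = 0.166, and 0.0351 with the block). Pecam1, the 1 stromal and endothelial gene measured, differed by -0.10 ± 0.08 (adjusted p = 0.477), and Xist, the 1 sex-linked gene measured, by 0.04 ± 0.10 (adjusted p = 0.836). The platelet and mitochondrial transcript lists had 0 measured members.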

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

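Voom precision weights were chosen after seeing the data, and the other alternatives before. The count of 306 genes became 993 with the replicate block, which used the pairs set out with the processing, and 78 in the test against a 1.2-fold change. It ran from 94 to 644 over fits that each left out 1 library: 155 without Ly49G+ replicate 1, 94 without Ly49G+ replicate 2, 168 without Ly49G+ replicate 3, 644 without Ly49I+ replicate 1, 207 without Ly49I+ replicate 2 and 293 without Ly49I+ replicate 3. The cause was not tested, but the 1.2-fold test asks for more by construction, and a fit without 1 library has less power. It was 236 without the trend, 328 with the robust prior, 223 of 7153 genes with a mean of at least 4, 323 after quantile normalization, 340 after median centring (193 higher in Ly49G+) and 292 with precision weights. The minimum mean of 1 removed no gene and says nothing of stability. The 8 lists past camera became 1 with an estimated correlation, and 8 passed with the block. Fry also passed 8, with trafficking receptors (adjusted p = 0.0305) in and ribosomal proteins (0.182) out. Over the Ly49 family 6 genes were called, and 9 with the block. No named gene that was called in the main fit or in an alternative turned its direction between them. Turns of genes called in neither fit were not counted. Of 87 named genes, 72 called, 29 lost their call in the 1.2-fold test, 28 without Ly49G+ replicate 2, 12 without Ly49G+ replicate 3, 10 without Ly49G+ replicate 1 and 7 without Ly49I+ replicate 2, 7 without the trend and 6 with the robust prior, while 11 gained one with the block and 0 lost one. The block changed no other named gene's call and no list's call. With 3 libraries per group, differences of 0.5 on the log2 scale were often missed in simulated data (46% called).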

Other observations

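Except for the split of the libraries and the search for shared Ly49 sequence, the tests in this part were chosen after the results were seen, as was the list of ribosome assembly factors.

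Of 67 measured ribosome assembly factors, 13 passed the limma test, all higher in Ly49G+, and 59 had a positive difference, with a median of 0.18 on the log2 scale. They include Npm1 (0.63 ± 0.08, adjusted p = 0.00295), the small nucleolar ribonucleoprotein gene Nop58 (0.54 ± 0.08), the pseudouridine synthase gene Dkc1 (0.49 ± 0.08) and the nucleolin gene Ncl (0.40 ± 0.08). With an estimated correlation camera gave a p of 0.0407 over the list. That test decides nothing by itself, because the list was written after several of its members had been seen among the called genes. A second test, added after the first, left out the 13 called genes: of the other 54, 46 had a positive difference, and the p with an estimated correlation was 0.138. Leaving out members because they were called, all in one direction, lowers the rest by construction, so this test decides nothing either.

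In the real grouping 306 genes were called, and 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many. The highest of the other splits gave 0, as did the highest of the other splits that part all 3 replicate pairs. With 10 splits no share under 0.05 can be reached.

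The first pattern is the RNA of Csf1r, Lyz2 and other genes far higher in Ly49I+ libraries. In the 27 genes at least 4-fold higher in Ly49I+, the excess over the Ly49G+ mean was a median 4.21 times larger in Ly49I+ replicate 2 than in the mean of replicates 1 and 3 (quartiles 3.91 and 4.56), against 1.0 in the other 122 genes higher in Ly49I+, which suggests, as a hypothesis, a few myeloid cells in unequal amounts despite the NK1.1 gate, with Lyz2 at 351.9 and Csf1r at 138.1 CPM in replicate 2. Against it, Cst3 stood at only 16.1 CPM in that library with a ratio of 1.85, so the kind of cell stays open. Of the 27 genes, 25 had a ratio above 2. Cx3cr1, a member of the CD11b+ stage list, had 1.09 and Kcnj8 0.70, so the hypothesis does not cover these genes. Sequencing depth is excluded for the unequal levels within Ly49I+, where replicate 2 lay a median 2.20 above replicate 3 on the log2 scale at a log2 depth ratio of 0.07. For the difference between groups, the median gap of 2.15 between Ly49I+ replicate 1 and the higher of Ly49G+ replicates 2 and 3 decides nothing. Choosing separated genes at least 4-fold higher largely sets that gap. The values are per library total, however, and all totals lay between 33599679 and 40892154 reads. A range so much smaller than 4-fold argues against depth as the main cause of the difference between groups. For the CD11b+ stage genes, the 15 called members had a median ratio of 0.98 (0.58 to 1.37). Calling favours genes of even level within Ly49I+ unless their difference is large. This ratio and that of the other 122 genes are therefore partly set by the choice of genes. The mean over all 22 measured CD11b+ stage members, called or not, was 8.268, 8.309 and 8.309 log2 CPM in Ly49I+ replicates 1, 2 and 3. In the Ly49G+ replicates it was 7.707, 7.785 and 7.715. That evenness within Ly49I+ argues against the same source for the list as a whole, and a difference in maturation between the populations stays open for it.

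The second pattern is the CD3 and T cell receptor RNA in Ly49G+ libraries. Cd3d, Cd3e, Cd3g and Trac had excesses 1.94 to 2.11 times larger in replicate 2 than in replicate 1. The ratios given for this pattern leave out replicate 3. The summed excess of Trbc1 and Trbc2 was 27.18 ± 3.69 CPM beside 12.14 ± 4.84 for Cd3e (SD over the Ly49G+ libraries, without the spread of Ly49I+). That would be enough for a few T cells in unequal amounts, but neither Trbc1 nor Trbc2 passed the limma test over all genes. The Trbc excess itself had a ratio of 1.31, and NK cells also carry Trbc RNA (Trbc1 109.4 or more in every library), so T cells that escaped the CD3 gate and NK cells with CD3 RNA cannot be told apart. Whether the same source could carry the immature stage genes was not settled. Their 12 called members had a median ratio of 1.36, from 0.93 to 1.84, below all 4 CD3 genes. That median was not within the limit of 1.3 set for ruling the source out. All 155 genes higher in Ly49G+, these included, had a median ratio of 1.23 (quartiles 1.03 and 1.51), so 1.36 lies near the general level of called genes.

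The third pattern is the Klra3 RNA in cells sorted as Ly49C/I-negative, at 123% of its level in Ly49I+ cells. Carry-over of Ly49I+ cells is argued against, since Klra9 kept only 7.32% of its level there. Reads shared exactly with other Ly49 genes are argued against too, since 1.8% of the 100-base windows of Klra3 transcripts occur in another Ly49 gene, although near-identical reads that differ by a few bases were not tested. A candidate explanation left open is that Klra3 RNA is present without enough Ly49C on the surface to be sorted as positive, which no measurement here tests.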
